A study of Rattus norvegicus with 6 samples.

How the data were processed

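Sciatic nerve tissue was collected from rats with chronic constriction injury (CCI), in which ligatures around the nerve produce lasting damage and neuropathic pain. Messenger RNA was sequenced in 3 libraries from untreated injured nerve and in 3 from injured nerve treated with a PLLA-PCL-RVC conduit, a polymer nerve wrap described in the labels as piezoelectric and carrying ropivacaine, a local anaesthetic. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made with the VAHTS Universal V10 kit after mRNA enrichment. The labels do not say whether strand was kept, so reads from a gene and an overlapping or antisense partner may not have been told apart. Whether each library came from a separate animal is not stated either, so p-values measure the spread between these libraries, which may be partly technical.

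The authors deposited a table of raw counts per gene, with 29884 genes and 1 column per library. They also deposited FPKM values (fragments per kilobase of gene, scaled by the library's total) per library. Per the submitters' processing notes, fastp, HISAT2, HTSeq and DESeq2 were used with the mRatBN7.2 build. The notes used here give no versions, roles or order. In all 20504 genes with FPKM above 0 in at least 2 libraries, the deposited FPKM equalled the count divided by 1 gene length and by the library's total, within a tolerance of 0.0001, so the FPKM values carry the same information as the counts scaled by library totals. Total counts ran from 38401951 to 42225086 per library. No row lacked a gene name, 0 columns were left unused, and 7834 genes had no count in any library. Gene symbols are those of the count table. Older symbols were matched through the RefSeq gene table of the GRCr8 assembly. Since that assembly is not the one named in the notes, no coordinates are given. Genes of large families, such as the MHC class I (RT1) genes, share sequence, and their reads may be split among copies.

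Gene tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, on counts of the 15464 genes kept by filterByExpr (minimum count 10). Libraries were scaled by TMM (trimmed mean of M-values), the model held the group alone, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM is the count relative to the library total after TMM scaling. Log2 fold changes are conduit minus untreated, and a gene with 1 to 3 counts in a whole group is given as a ratio of pooled CPM with an exact Poisson 95% interval for the low count. A gene at 0 in a whole group is given as a bound computed from 3 counts in each library. Such intervals and bounds cover counting error only, since PCR duplicates are not independent molecules. Sample separation was described with principal components and with Spearman correlations of log2 CPM (prior count 2), compared between and within groups by an exact permutation test over 10 splits.

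Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 33 lists. The same test was repeated with the correlation estimated per list and with fry, which asks only whether a list's members move one way on balance. The 12 study-themed lists cover myelin, repair Schwann cells, neurotrophic factors, inflammatory cytokines, pro-inflammatory and alternatively activated macrophage states, foreign body cells, extracellular matrix, pain-related channels, mechanosensing, angiogenesis and complement. The other 21 lists mark cell types, tissue composition, metabolism and RNA quality. The tissue was bulk nerve, so a cell type named below stands for its marker genes only. One skeletal muscle symbol, Mylpf, had no match. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except those that the closing section names as chosen later. The rule names the 6 highest and 6 lowest log2 fold changes among called genes with at least 5 CPM in the higher group and no overlap of libraries. It adds up to 3 members with the smallest adjusted p of each study-themed list, and the 2 most abundant members of each marker list. Of the marker genes, those of shifted lists, skeletal muscle and adipocytes are printed, a choice made after the values were seen. Genes behind a list's count of 5 or fewer and other named genes were also chosen after their values were seen. A further 4 genes considered were dropped, partly because their calls were lost under alternatives, and the closing section gives how often. Some genes that the rule names are not reported here.

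Alternatives were DESeq2 1.42.0, RLE scaling, library totals alone, no low-count filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, robust dispersions, limma on log2(FPKM + 1) for genes with FPKM of at least 0.5 in 3 libraries, the same with a pseudocount of 0.1 or without the filter, and each library left out in turn. The closing section gives their effect. The tests were tried on simulated data for this comparison, with 200 of 15464 genes changed. edgeR recovered 2% of genes changed 1.5-fold, 22% at 2-fold, 82% at 4-fold and 90% at 8-fold, and 6 of its 104 calls were unchanged genes. DESeq2 recovered 62% at 2-fold, with 52 unchanged genes among 177 calls. camera called the changed list of 20 genes, and 0 of 30 unchanged lists, with both the preset and the estimated correlation, and fry called the changed list and 1 of the 30 unchanged lists. Genes were simulated independently of one another, so these list results say nothing about lists whose members vary together.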

Results

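Gene expression was measured by RNA sequencing in 6 libraries from rat sciatic nerve with chronic constriction injury, 3 untreated and 3 treated with the PLLA-PCL-RVC conduit. The time after injury is not given in the labels for either group. Library totals were 41464511, 41879724 and 38401951 counts in untreated replicates 1, 2 and 3, and 41939798, 41524084 and 42225086 counts in the conduit replicates. Group values below are mean CPM ± SD of 3 libraries, and gene p-values are Benjamini-Hochberg adjusted values from edgeR. The first principal component held 76.4% of the variance. The mean Spearman correlation was 0.979 within groups and 0.882 between groups, a difference of 0.0964 (exact permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). The labels carry 5 batch numbers, 2 in the untreated and 3 in the conduit group, and no batch holds both groups. Libraries of 1 group with different batch numbers correlated at 0.970 to 0.991, the 2 of 1 group and batch at 0.965, and libraries of different groups at 0.866 to 0.911. A difference shared by all batches of 1 group cannot be told apart from treatment in any result here.

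The single comparison of the design asks which genes differ between conduit-treated and untreated injured nerves, with pain modulation, Schwann cell repair and inflammation as its stated themes. By gene lists, conduit nerves had higher myelin and cholesterol synthesis genes and lower macrophage, cytokine and proliferation genes, while of 23 repair Schwann cell genes 16 fell and 5 rose. With an estimated correlation none of these 6 list calls held (adjusted p = 0.19 for myelin, 0.15 for cholesterol, 0.13 for macrophages, 0.069 for cytokines, 0.16 for proliferation and 0.069 for repair). Mbp, myelin basic protein, made up 2.15 ± 0.281% of counts in conduit nerves and 0.312 ± 0.0660% in untreated nerves (SD, n = 3). Mki67, a marker of dividing cells, went the other way, at 3.48 ± 1.61 CPM against 75.0 ± 7.06 CPM. Of 15464 genes tested, 7760 changed, 3711 of them higher and 4049 lower in conduit nerves. At least 2-fold differences were found for 4601 genes, 2261 higher and 2340 lower. The 2 groups did not overlap in 7692 of the changed genes, which being called with 3 against 3 libraries largely implies, and in 61.7% of all tested genes. For a single gene without a difference, chance gives 10%. Genes vary together, so that value is no test of the share over all genes.

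The highest fold changes included Cyp1a1, a xenobiotic-metabolising cytochrome, with 31.8 ± 17.8 CPM in conduit nerves and 1 count in the untreated group as a whole. Its pooled ratio was 4473 (95% counting interval 803 to 176680, adjusted p = 0.000114). Oprk1, the kappa opioid receptor, rose from 0.102 ± 0.0365 to 8.10 ± 1.17 CPM (log2 fold change 6.28 ± 0.36 SE). St8sia2, a polysialic acid synthase, rose from 0.564 ± 0.668 to 46.2 ± 5.31 CPM. B3galt2 (6.25 ± 0.28), Slc24a2 (6.70 ± 0.87) and Ddn (6.20 ± 0.72) completed the 6 highest log2 fold changes. Without untreated replicate 3, St8sia2 was at 7.998 (6.38 with all libraries) and Ddn at 7.63, and Slc24a2 was at 7.82 without untreated replicate 1 and 6.11 without untreated replicate 2. The 1 untreated count of Cyp1a1 was in replicate 3, and its log2 fold change with all libraries was 11.61. Without untreated replicate 3 the untreated group was at 0 counts, so no fold change is given for that setting. Among the lowest, Vgf, a secreted neuropeptide precursor, was at 16.4 ± 3.85 CPM in untreated nerves and at 0 counts in every conduit library, which is at least 200.4-fold lower in the conduit group. Ucn2, urocortin 2, fell from 272 ± 66.6 to 0.443 ± 0.260 CPM. Cd8b, a T cell co-receptor chain, had 2 counts in the conduit group, a ratio of 368 in favour of the untreated group (95% counting interval 102 to 3037). Syt4 (-8.48 ± 0.86) and Clca4l (-8.52 ± 1.00) also fell. They were at -7.62 and -7.45 without untreated replicate 2, and Clca4l was at -9.17 without conduit replicate 3. Tnni2, a fast muscle troponin, met the same rule at -8.91 ± 2.60, with 575 CPM in untreated replicate 1 and 3.29 and 0.897 CPM in the other untreated libraries. Without untreated replicate 1 it was at -2.39, and its call was lost without conduit replicate 1, 2 or 3 (adjusted p = 0.0767, 0.0785 and 0.0695).

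Of 20 myelin genes, 19 rose and Gldn fell, with the same counts adjusted over the list alone, and the median log2 fold change was 3.03. Mbp rose from 2740 ± 627 to 24623 ± 3412 CPM (log2 fold change 3.17 ± 0.24 SE, adjusted p = 0.000114). Drp2 (2.70 ± 0.16), a protein of the periaxin complex, rose as well. Gldn, gliomedin of the node of Ranvier, was at -0.70 ± 0.19 (adjusted p = 0.0203). It lost its call without untreated replicate 3 (adjusted p = 0.0507), conduit replicate 1 (0.0726) or conduit replicate 3 (0.0927). All 17 cholesterol synthesis genes rose, also adjusted over the list alone, with a median of 2.51. Hmgcs1, which makes the precursor of mevalonate, rose from 184 ± 38.6 to 2401 ± 275 CPM. The summed adipocyte markers, cells that also make lipids, were highest in conduit replicate 3, at 5769 CPM. They were 1468 and 1589 CPM in the other conduit libraries and 786 to 2406 CPM in the untreated libraries. Adjusted p was 0.19 for the myelin list and 0.15 for the cholesterol list with an estimated correlation.

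Repair Schwann cell genes moved apart. Of 23 tested, 16 fell and 5 rose, with 17 and 5 adjusted over the list alone (adjusted p = 0.069 with an estimated correlation). The members that fell included the secreted factors Clcf1 (-6.39 ± 0.26) and Lif (-5.37 ± 0.28), Ucn2 and Gdnf, and Ngfr, the low-affinity neurotrophin receptor, which went from 597 ± 125 to 48.6 ± 15.1 CPM. The 5 that rose were the adhesion molecules Ncam1 (2.39 ± 0.27) and L1cam (2.18 ± 0.25), the lineage factor Sox10 (1.26 ± 0.13), Erbb3 (0.49 ± 0.14) and Olig1 (1.77 ± 0.56), of which Sox10 and Erbb3 are expressed throughout the Schwann cell lineage. Erbb3 did not pass with scaling by library totals (0.10, adjusted p = 0.532), nor without untreated replicate 1 (adjusted p = 0.0559), conduit replicate 1 (0.0796) or conduit replicate 2 (0.0930). The list had 3 genes higher with library totals, with limma on FPKM or without untreated replicate 1. Olig1 did not pass without untreated replicates 1, 2 or 3 (adjusted p = 0.0650, 0.0553 and 0.0919) or conduit replicate 3 (1.16, adjusted p = 0.120). All 18 proliferation genes fell, also adjusted over the list alone, with a median of -3.44 and an adjusted p of 0.16 with an estimated correlation. Mki67 fell by 4.43 and Pcna, a DNA replication clamp, by 0.78 on the log2 scale.

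**Figure D1:**
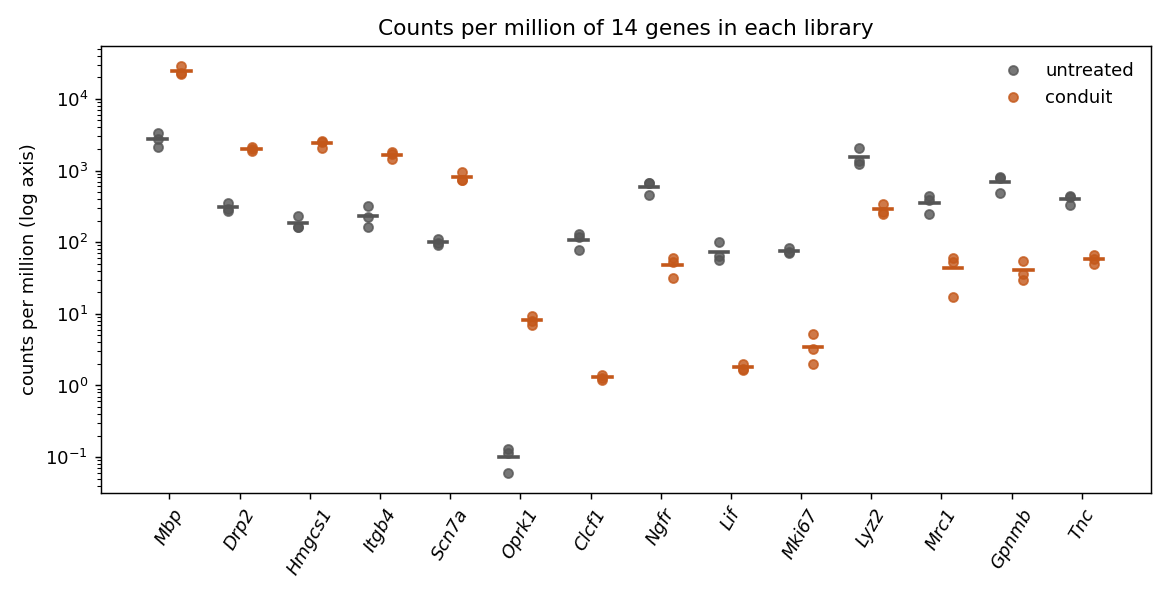
CPM (log axis) of named genes in each library, grey for untreated and orange for conduit nerves, with points for libraries and bars for group means of 3. Mbp was 2124 to 3377 CPM in untreated and 22257 to 28534 CPM in conduit libraries, and Gpnmb was 492 to 806 CPM against 29.9 to 55.3 CPM.

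Macrophage and cytokine genes were lower in conduit nerves. All 18 macrophage markers fell, also adjusted over the list alone, with a median of -2.99 (adjusted p = 0.13 with an estimated correlation). Lyz2, lysozyme, went from 1539 ± 456 to 287 ± 50.0 CPM, and Mrc1, the mannose receptor, from 357 ± 97.9 to 43.2 ± 22.8 CPM. Of 20 inflammatory cytokine and chemokine genes, 14 fell, or 18 adjusted over the list alone, and 0 rose (adjusted p = 0.069 with an estimated correlation). They included Il18 (-3.26 ± 0.25), Tgfb1 (-1.65 ± 0.13) and Il1rn (-5.28 ± 0.44), whose product blocks the interleukin-1 receptor. Both macrophage activation lists fell, with medians of -2.55 (pro-inflammatory) and -2.92 (alternatively activated) beside the -2.99 of the macrophage markers. They share members with the macrophage list, such as Fcgr1a and Mrc1. In bulk nerve these values do not tell the number of macrophages from their state. The pro-inflammatory list had 10 of 13 lower, 12 adjusted over the list alone, with 1 higher, Cxcl9 (adjusted p = 0.069 with an estimated correlation). Its members with the smallest adjusted p were Tlr2 (-3.92 ± 0.24), Fcgr1a (-3.43 ± 0.23) and Irf5 (-2.92 ± 0.25). Cxcl9, an interferon-induced chemokine, was at 1.18 ± 0.36 (adjusted p = 0.0293). It did not pass without untreated replicate 1 (0.0679), untreated replicate 2 (0.0758) or conduit replicate 1 (log2 fold change 0.77, adjusted p = 0.0880). The alternatively activated list had 11 of 12 lower by either adjustment, among them Il4r (-2.31 ± 0.12) and Folr2 (-3.16 ± 0.34), with an adjusted p of 0.18 with an estimated correlation.

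Other immune lists were lower as well. In the foreign body list, 6 of 10 genes fell and 2 rose by either adjustment (adjusted p = 0.15 with an estimated correlation). Gpnmb (-4.10 ± 0.32), Trem2 (-2.21 ± 0.18) and Cd44 (-2.34 ± 0.22) fell. Spp1, osteopontin, rose (0.82 ± 0.18), as did Acp5, an acid phosphatase of osteoclasts (0.90 ± 0.26), which did not pass without untreated replicate 1 or conduit replicate 1 or 2 (adjusted p = 0.0586, 0.0521 and 0.0665). Of 17 complement genes 10 fell by either adjustment (adjusted p = 0.58 with an estimated correlation), among them the receptors C3ar1 (-3.79 ± 0.19) and C5ar1 (-3.45 ± 0.23), and Cfp, properdin (-2.34 ± 0.37). Of 14 T and NK cell genes 12 fell (adjusted p = 0.27 with an estimated correlation), including Cd8a (-6.63 ± 0.57) and Cd4 (-1.50 ± 0.36). Of 7 B and plasma cell genes 5 fell (adjusted p = 0.19 with an estimated correlation), namely Blnk (-3.28 ± 0.38), Cd22 (-2.51 ± 0.46, or -3.19 without conduit replicate 3), Cd79a (-2.12 ± 0.46), Jchain (-1.90 ± 0.39) and Derl3 (-0.98 ± 0.31). Derl3 did not pass without untreated replicate 1 or 2 or conduit replicate 1, 2 or 3 (adjusted p = 0.105, 0.0539, 0.0680, 0.119 and 0.0716). In the MHC class II list only RT1-DMa (-1.91 ± 0.31), RT1-DMb (-1.79 ± 0.31) and Itgax (-3.21 ± 0.40) of 12 passed (adjusted p = 0.71 with an estimated correlation), while Cd74 was at -0.58 ± 0.40 and RT1-Da at -0.78 ± 0.48. With single libraries left out, Cd74 ran from -0.85 (without untreated replicate 2) to -0.078 (without untreated replicate 3), and RT1-Da from -1.25 (without conduit replicate 3) to -0.26 (without untreated replicate 3). The number lower in this list was 6 with DESeq2 or without untreated replicate 2, 7 with a replicate block, 8 with library totals, 5 without conduit replicate 3, and 7 with filtered or 5 with unfiltered FPKM. The MHC class II list did not pass without untreated replicate 3 (camera adjusted p = 0.0928), with library totals (0.103) or by fry (0.0614), and the B and plasma cell list did not pass with library totals (0.0727). The T and NK cell, B and plasma cell and MHC class II lists had the same counts adjusted over the list alone. Lists share members, for example the C1q genes, which stand in both the macrophage and the complement list.

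Genes of the pain theme and of growth factors went both ways. Of 18 pain-related channel and neuropeptide genes 10 rose and 3 fell, 11 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0654). It passed as higher with library totals (0.0236), without the 10 most abundant genes (0.0455) and by fry (0.00129), and with filtered FPKM 5 of 10 genes tested rose. Scn7a, a sodium channel of Schwann cells and sensory neurons, rose from 99.9 ± 9.35 to 806 ± 117 CPM (3.01 ± 0.17). Trpv1, the capsaicin receptor (2.66 ± 0.60, or 3.71 without untreated replicate 3), rose to 5.07 ± 0.737 CPM in conduit nerves, and Cacna1b (-2.71 ± 0.33), P2rx4 (-1.14 ± 0.22) and Asic2 (-1.38 ± 0.49) fell. Asic2 did not pass without untreated replicate 1 or 2 or conduit replicate 1, 2 or 3 (adjusted p = 0.0912, 0.145, 0.0543, 0.163 and 0.133). Of 23 neurotrophic factor and receptor genes 8 rose and 9 fell, 8 and 12 adjusted over the list alone (camera adjusted p = 0.0654), with Nrg1, neuregulin 1, at -4.43 ± 0.27. This list passed as lower without untreated replicate 1, 2 or 3 (adjusted p = 0.0456, 0.0382 and 0.0193), without the low-count filter (0.0238), with a replicate block (0.0253) and by fry (0.000991). The mechanosensing list had 7 of 18 higher and 4 lower, 7 and 5 adjusted over the list alone (camera adjusted p = 0.245, and 0.0289 by fry). Piezo2, a mechanically gated channel (1.43 ± 0.15), Ajuba (1.87 ± 0.19) and Amotl2 (1.73 ± 0.19) were among those higher, and Piezo1 (-1.09 ± 0.18), Trpv4 (-0.89 ± 0.30), Ccn1 (-1.20 ± 0.30) and Ankrd1 (-4.44 ± 1.49) were lower. Ankrd1 was at -0.92 without untreated replicate 1 (adjusted p = 0.233), the library with the muscle transcripts, and did not pass without conduit replicate 1, 2 or 3 (0.108, 0.113 and 0.0955). Trpv4 did not pass without untreated replicate 2 or 3 or conduit replicate 1 or 3 (adjusted p = 0.0853, 0.114, 0.145 and 0.134). Ccn1 did not pass without conduit replicate 1 (0.0533), and was at -0.77 without untreated replicate 3. In the extracellular matrix list 6 of 22 fell and 3 rose, 6 and 2 adjusted over the list alone (camera adjusted p = 0.245). Tnc (-2.77 ± 0.19), Thbs2 (-2.44 ± 0.19) and Timp1 (-2.00 ± 0.16) fell, whereas Sparc (1.45 ± 0.23), Col1a1 (1.44 ± 0.42) and Col1a2 (1.25 ± 0.43) rose. Col1a1 did not pass without untreated replicate 1 or 2 or conduit replicate 2 or 3 (adjusted p = 0.0749, 0.0675, 0.0650 and 0.0602), nor did Col1a2 (0.120, 0.113, 0.103 and 0.107). This list had 6 genes higher without untreated replicate 3, 5 without conduit replicate 1, 6 with DESeq2 and 7 with a replicate block. Of 16 angiogenesis genes 2 rose and 6 fell by either adjustment (camera adjusted p = 0.245), with Aplnr, the apelin receptor, at -3.10 ± 0.27, Angpt1 at -1.21 ± 0.26, Pgf at 1.64 ± 0.25 and Robo4 at 0.71 ± 0.15.

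**Figure D2:**
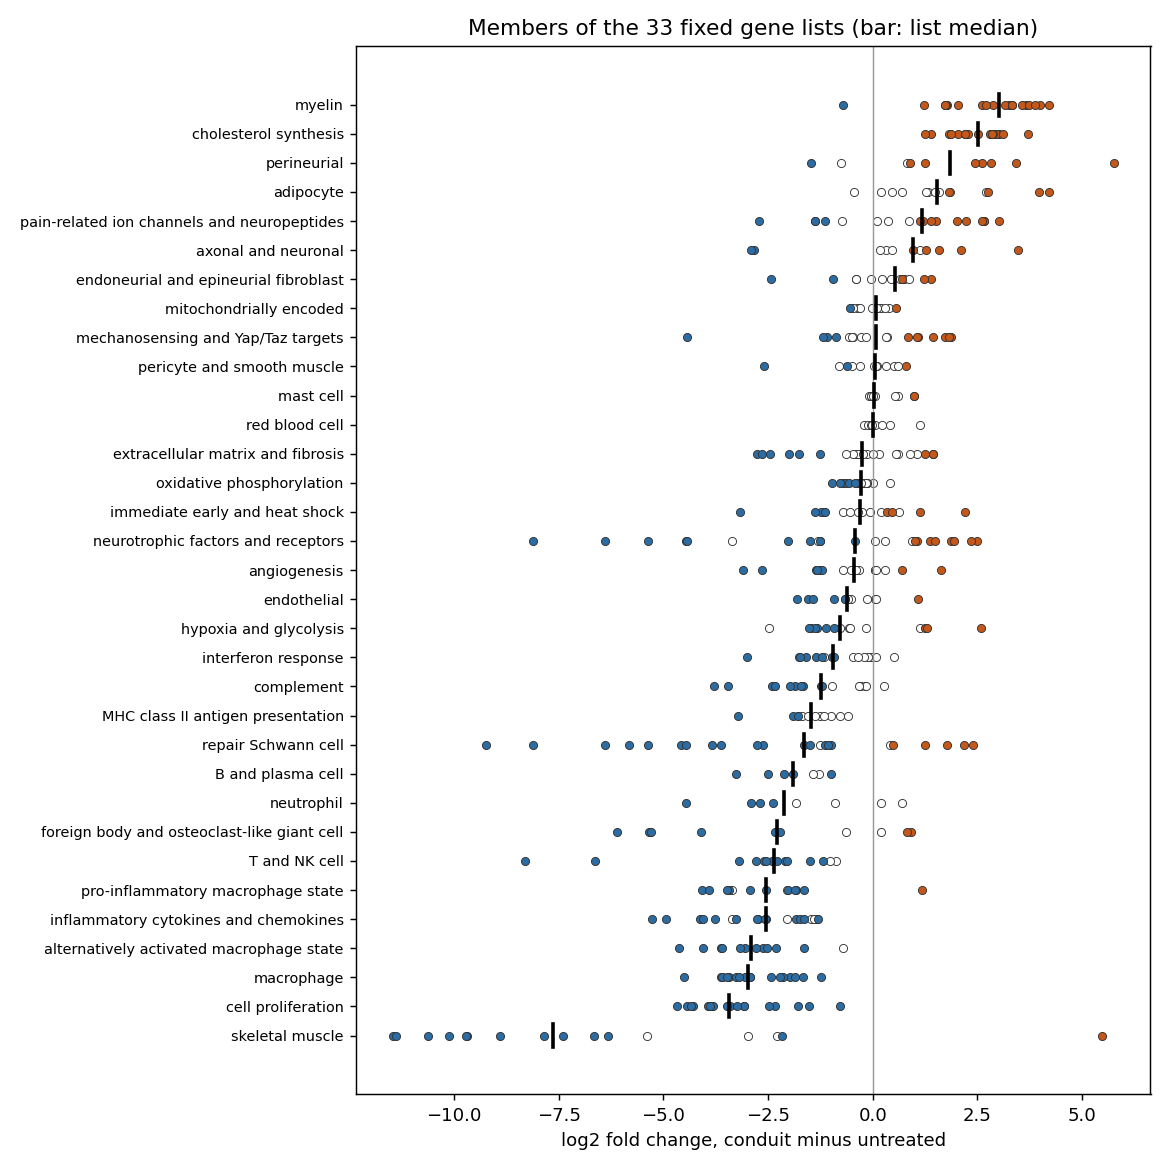
Log2 fold changes, conduit minus untreated, of the tested members of the 33 fixed lists, with lists ordered by their median (black bar) and points filled where an adjusted p under 0.05 was reached, orange when higher and blue when lower. Myelin (median 3.03) and cholesterol synthesis (2.51) stand at the top, and skeletal muscle (-7.63) and proliferation (-3.44) at the bottom. The skeletal muscle list did not pass (camera adjusted p = 0.409), and its median was -2.02 without untreated replicate 1.

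Markers of other tissues differed between single libraries. Of 16 skeletal muscle genes 12 fell and Myh7, the slow and cardiac myosin, rose (5.48 ± 0.47), by either adjustment, and the list did not pass (camera adjusted p = 0.409, and 0.0232 without untreated replicate 3). Summed muscle markers were 14281 CPM in untreated replicate 1, 110 and 20.04 CPM in untreated replicates 2 and 3, and 32.8 to 35.4 CPM in conduit libraries. Acta1 was at 3857, 35.0 and 2.49 CPM in the untreated libraries and Ckm at 3134, 18.9 and 0.0690 CPM. Without untreated replicate 1 the list had 7 genes lower and 4 higher, with a median of -2.02. Only 1 passed as lower without conduit replicate 1, 2 or 3, where the list medians were -8.27, -7.80 and -8.28, and only 1 with DESeq2, with robust dispersions, with a replicate block or with limma on FPKM, and 15 were lower without untreated replicate 3. Without untreated replicate 1 Acta1 was at -3.58 and Ckm at -4.62. Acta1 lost its call without conduit replicate 1, 2 or 3 (adjusted p = 0.0722, 0.0745 and 0.0526), at log2 fold changes of -9.29, -9.39 and -10.64. Ckm lost its call without untreated replicate 1 (0.0779) or conduit replicate 1, 2 or 3 (0.0878, 0.0861 and 0.0640), the latter at -11.07, -10.81 and -13.30. Of 14 adipocyte genes 4 rose, Lep (leptin, 4.21 ± 0.61), Pnpla3 (3.97 ± 0.60), Cidec (2.76 ± 0.92) and Lpl (1.82 ± 0.34), or 3 adjusted over the list alone (camera adjusted p = 0.0654), while Car3 was at 1.48 ± 0.75, or 0.40 without conduit replicate 3, and Cfd at 0.19 ± 0.68. The list passed as higher under 7 of 13 alternatives: without conduit replicate 1 (adjusted p = 0.00487), conduit replicate 2 (0.0153) or untreated replicate 3 (0.0225), with library totals (0.0124), without the low-count filter (0.0238), without the 10 most abundant genes (0.0455), and with a replicate block (7.61e-05), where 10 of 14 genes were higher. Without conduit replicate 3 it had 3 genes higher and 1 lower, with a median of 0.39. Cidec did not pass without untreated replicate 1 or 2 (adjusted p = 0.0807 and 0.108) or conduit replicate 3 (1.53, adjusted p = 0.131). Without untreated replicate 3 it was at 3.84 and Pnpla3 at 4.72. Of 10 perineurial genes 7 rose by either adjustment (adjusted p = 0.33 with an estimated correlation), including Itgb4 (2.82 ± 0.26) and the glucose transporter Slc2a1 (1.24 ± 0.15). The 1 that fell, Msln (-1.47 ± 0.45), did not pass without untreated replicate 3 (-0.95, adjusted p = 0.0892) or conduit replicate 1 or 2 (adjusted p = 0.0850 and 0.0899).

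**Figure D3:**
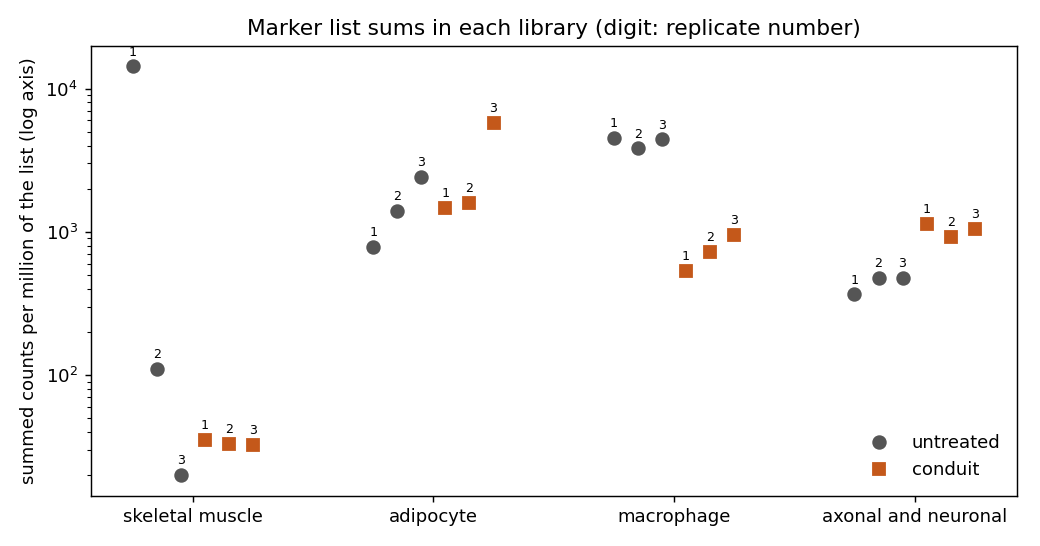
Summed CPM (log axis) of the members of marker lists in each library, circles for untreated and squares for conduit nerves, with the replicate number above. Muscle markers reached 14281 CPM in untreated replicate 1 and at most 110 CPM elsewhere, and macrophage markers were 3821 to 4513 CPM in untreated and 533 to 955 CPM in conduit libraries.

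The remaining marker lists did not pass (camera adjusted p from 0.0654 to 0.866), although 4 of them gained a call under some of 13 alternatives. The axonal and neuronal list passed as higher without conduit replicate 2 (adjusted p = 0.0245), with library totals (0.0349), without the low-count filter (0.0430), with a replicate block (0.0411) and by fry (0.0251). The endothelial list passed as lower without untreated replicate 1 (0.0425) or conduit replicate 3 (0.0339), without the filter (0.0425), with the block (0.0336) and by fry (0.0289). The interferon list passed as lower without untreated replicate 2 (0.0382) or conduit replicate 1 or 3 (0.0411 and 0.0268), without the filter (0.0272) and with the block (0.0201), and the neutrophil list without conduit replicate 2 (0.00358), without the filter (0.0425) and by fry (0.00736). Of 11 axonal and neuronal genes 5 rose and 2 fell by either adjustment. Tubb4a (3.47 ± 0.28), Snap25 (2.11 ± 0.64), Stmn2 (1.59 ± 0.32), Sncg (1.27 ± 0.16) and Uchl1 (0.96 ± 0.17) rose, and Snap25 did not pass without untreated replicate 1 or 3 or conduit replicate 1 (adjusted p = 0.0699, 0.0754 and 0.111, the last at a log2 fold change of 1.42). Those that fell were the neurofilaments Nefl (-2.85 ± 1.00) and Nefm (-2.91 ± 0.74), with Nefl at 2.25 CPM in untreated replicate 1 and 83.5 and 45.0 CPM in the other untreated libraries. Nefl lost its call without untreated replicate 2 or 3 or conduit replicate 1, 2 or 3 (adjusted p = 0.141, 0.0835, 0.118, 0.116 and 0.117), and Nefm without conduit replicate 2 (0.0522). Without untreated replicate 2 Nefl was at -1.96 and Nefm at -2.01. Genes that rose and fell numbered 0 and 4 of 8 for neutrophils, 1 and 5 of 12 for endothelium, 3 and 2 of 14 for fibroblasts, and 0 and 8 of 16 for the interferon response, by either adjustment. They numbered 4 and 5 of 16 for immediate early and heat shock genes by either adjustment, and 0 and 6 of 20 for oxidative phosphorylation (0 and 5 adjusted over the list alone). Lower oxidative phosphorylation genes numbered 17 of 20 with library totals and with filtered FPKM, and 15 with unfiltered FPKM. Interferon genes lower numbered 4 without conduit replicate 2, and neutrophil genes 2 without conduit replicate 1. Genes higher numbered 5 for hypoxia and glycolysis without untreated replicate 1, 3 for mitochondrially encoded genes without untreated replicate 2, 6 and 5 for fibroblasts without untreated replicate 3 and conduit replicate 1, 2 for pericytes without untreated replicate 3, and 2 for mast cells without conduit replicate 2. Hypoxia and glycolysis genes gave 3 and 6 of 15, or 4 and 7 adjusted over the list alone. Pericyte and smooth muscle genes gave 1 and 2 of 12 (1 and 1 adjusted over the list alone), with a median of 0.05 and a mean of -0.20. Mast cell genes gave 1 and 0 of 10 and mitochondrially encoded genes 1 and 1 of 13, and none of these passed adjusted over the list alone. None of 9 red blood cell genes passed by either adjustment.

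Among neutrophil genes Csf3r (-4.46 ± 0.37), S100a9 (-2.91 ± 0.56), S100a8 (-2.68 ± 0.69) and Cxcr2 (-2.37 ± 0.77) fell. S100a8 did not pass without conduit replicate 1 (adjusted p = 0.0528), nor did Cxcr2 without untreated replicate 2 or 3 or conduit replicate 1 or 2 (0.104, 0.0585, 0.0649 and 0.0959). S100a8 was at -3.42 without conduit replicate 2 and Cxcr2 at -3.05 without conduit replicate 3. Cldn5, a tight junction protein, rose (1.08 ± 0.28) while the endothelial genes Plvap (-1.80 ± 0.39), Tie1 (-1.54 ± 0.19), Egfl7 (-1.44 ± 0.13), Pecam1 (-0.93 ± 0.22) and Esam (-0.65 ± 0.12) fell. Of pericyte and smooth muscle genes Cspg4 rose (0.79 ± 0.15) and Actg2 (-2.60 ± 0.48, or -3.34 without conduit replicate 2) and Kcnj8 (-0.61 ± 0.19) fell. Kcnj8 did not pass without untreated replicate 1 or 2 or conduit replicate 1 or 2 (adjusted p = 0.0621, 0.0746, 0.109 and 0.119). Of fibroblast genes Etv1 (1.40 ± 0.19), Osr2 (1.22 ± 0.25) and Cd55 (0.71 ± 0.16) rose and Ly6c (-2.44 ± 0.34) and Pdgfra (-0.95 ± 0.31) fell. Pdgfra did not pass without untreated replicate 2 or 3 or conduit replicate 1 or 2 (adjusted p = 0.0677, 0.0968, 0.0518 and 0.0520). The mast cell gene that rose was Tpsb2 (0.98 ± 0.26). Of immediate early and heat shock genes Nr4a1 (2.20 ± 0.26), Hspa1a (1.12 ± 0.18), Dnajb1 (0.47 ± 0.10) and Hsph1 (0.34 ± 0.11) rose and Fos (-3.16 ± 0.33), Ier3 (-1.38 ± 0.23), Egr1 (-1.24 ± 0.28), Junb (-1.17 ± 0.13) and Ier2 (-1.14 ± 0.13) fell. The Hsph1 log2 fold change changed sign with library totals (-0.047), and the gene did not pass without untreated replicate 1 or 3 or conduit replicate 1, 2 or 3 (adjusted p = 0.0524, 0.0915, 0.0949, 0.0821 and 0.0752). Of hypoxia and glycolysis genes Ndrg1 (2.60 ± 0.23), Bnip3 (1.29 ± 0.20) and Slc2a1 rose. Of mitochondrially encoded genes ND2 rose (0.56 ± 0.19) and COX2 fell (-0.55 ± 0.19). ND2 did not pass without untreated replicate 1 or 3 or conduit replicate 1, 2 or 3 (adjusted p = 0.110, 0.0992, 0.0815, 0.0986 and 0.0951), nor did COX2 without untreated replicate 1 or 2 or conduit replicate 1, 2 or 3 (0.107, 0.0922, 0.0522, 0.159 and 0.159).

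By camera with the preset correlation, 14 of the 33 lists shifted, 3 up and 11 down, with adjusted p from 1.55e-22 to 0.0290. With an estimated correlation the count was 0 (lowest adjusted p = 0.069, with 8 lists at an unadjusted p under 0.05) and fry called 19. Of the 9 other splits of the same 6 libraries, 8 shifted as many lists or more at the preset correlation (13 to 23 over all of them). Those splits are unbalanced between the groups and can carry part of a group difference, so they are no reference for libraries without one. Of the changed genes, 47.8% were on the higher side with TMM, and 38.8% with totals that left out the 10 most abundant genes. TMM assumes that most genes are unchanged, yet 50.2% of tested genes were called. The balance of higher and lower genes therefore rests partly on the choice of scaling. Scaling by library totals, which does not correct for a few abundant transcripts, put 25.9% on the higher side. It shifted the median of all genes by -0.39 on the log2 scale. With that scaling the medians of the mechanosensing, pericyte, mast cell, red blood cell and mitochondrially encoded lists changed sign, the extracellular matrix list had 1 gene higher and 10 lower, 8 mechanosensing, 8 endothelial and 5 pericyte genes were lower, and Erbb3, Olig1, Col1a1, Col1a2, Cxcl9, Spp1, Acp5, Robo4, Cidec, Snap25, Cldn5, Cd55, Tpsb2, Dnajb1 and ND2 did not pass.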

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

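Leaving out the 10 most abundant genes, the list test with library totals, and leaving out libraries from the sample separation were chosen after the data had been seen. All 14 shifted lists kept their direction under the 13 alternatives run for them, and besides the estimated correlation the B and plasma cell list lost its call under 1 alternative and the MHC class II list under 3. Of the 19 lists that did not pass, 9 gained a call under at least 1 alternative, 36 calls in all, each in the list's own direction. Genes changed numbered 7760, with 8388 by DESeq2, 8845 with library totals and 7944 without the 10 most abundant genes. The count of genes higher in conduit nerves moved from 3711 to 2291 with library totals and to 2044, 2034 and 2254 with limma on FPKM at a pseudocount of 1, of 0.1, and without a filter. The count of genes lower in conduit nerves moved from 4049 to 6554 with library totals and 6263 with unfiltered FPKM. These settings all divide by library totals, which moved the median gene by -0.39. Leaving out single libraries gave 5840 to 7882 genes changed, 2921 to 3774 higher, 2919 to 4108 lower, 4138 to 4767 changed at least 2-fold and 16 to 17 lists. Lists shifted fell from 14 to 0 with an estimated correlation, by construction a wider test for lists whose members vary together. The between-group and within-group correlation difference was 0.0844 to 0.106 with single libraries left out and up to 0.781 with the 500 most variable genes, which by construction differ most between libraries, with p = 0.1 in each exact permutation test. Of 150 genes followed, under 2509 gene and setting pairs, 2288 kept direction and call, 206 lost the call (37 genes), 3 gained one and 12 changed sign (3 genes). Of 17 marker genes that the rule names and the text does not print, 8 changed sign in 44 of 287 pairs, none of them past the threshold, 2 lost calls in 9 pairs, and calls were gained in 18. The 4 genes considered and dropped lost their call in 22 of 65 pairs. The Cfd log2 fold change changed sign with library totals (-0.18) and with FPKM (-0.16 at both pseudocounts and unfiltered), and ran from -0.63 to 1.08 with single libraries left out. The Hsph1 log2 fold change, 0.34 and past the threshold, changed sign with library totals (-0.047) and with FPKM (-0.045 at a pseudocount of 1 and unfiltered, and -0.047 at 0.1), settings that move the median gene down, and ran from 0.31 to 0.39 with single libraries left out. The RT1-CE16 log2 fold change ran from -3.47 to 2.09, the latter without untreated replicate 3. The cause of the sign changes of Cfd and RT1-CE16 was not tested, and neither gene passed. Deviations of same-numbered libraries correlated at 0.14, -0.03 and 0.06, and those of different-numbered libraries at -0.15 to 0.10. These few values cannot decide whether the replicate numbers pair the samples. The replicate numbers are those of the titles, while the library names number the conduit libraries 2 to 4, so the block may match other libraries than intended. With the replicate block 7514 genes and 19 lists passed. On simulated counts of this depth with 200 of 15464 genes changed, 22% of 2-fold changes were recovered, a share that holds for that number of changed genes only.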

Other observations

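The lists in the next 2 paragraphs, and the tests of Schwann cell share, of batch labels within groups and of RT1-A3, were chosen only after the results had been seen, and leaving out the 10 most abundant genes was added after the data had been seen. These 7 lists were picked for changes already seen, so their p-values describe the genes listed and are not independent evidence. Of 13 fatty acid synthesis genes 12 rose by either adjustment, with a median log2 fold change of 1.76 (camera adjusted p = 8.38e-12 over 7 lists). With an estimated correlation the adjusted p was 0.032 over these 7 lists, and it was 0.063, not past the threshold, over 40 lists with the 33 fixed ones. Fasn, fatty acid synthase, went from 114 ± 15.9 to 929 ± 244 CPM and Scd, a desaturase, from 27.9 ± 5.46 to 455 ± 252 CPM (SD, n = 3). Scd was highest, at 740 CPM, in conduit replicate 3, the library with the most adipocyte marker counts. Of 15 cartilage-type matrix genes 11 rose by either adjustment, with a median of 3.27 (camera adjusted p = 2.42e-05, and adjusted p = 0.12 with an estimated correlation). Col2a1 went from 18.0 ± 13.5 to 442 ± 42.3 CPM, and Col9a2 (4.72 ± 0.66, or 5.37 without untreated replicate 3) and Epyc (5.81 ± 0.94) also rose.

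The labels give no hour of harvest for either group. All 10 circadian clock output genes rose by either adjustment, with a median of 1.56 and Hlf at 2.65 ± 0.33 (adjusted p = 0.12 with an estimated correlation). Of 5 genes of the opposite clock phase 1 fell, and 0 passed adjusted over the list alone, with a median of 0.11 and a mean of -0.10 (camera adjusted p = 0.986). Of 15 glucocorticoid-induced genes 8 rose and 2 fell by either adjustment (adjusted p = 0.53 with an estimated correlation). Tsc22d3 (3.08 ± 0.40) and Klf15 (3.66 ± 0.46) rose while the metallothionein Mt2A fell (-2.35 ± 0.40). Of 7 aryl hydrocarbon receptor targets 4 rose by either adjustment, including Cyp1a1, Tiparp (1.20 ± 0.15) and Nqo1 (1.14 ± 0.13) (adjusted p = 0.12 with an estimated correlation). Of 73 cytosolic ribosomal protein genes 64 fell, 70 adjusted over the list alone, with a median of -0.86, or -0.51 after a trend with gene length was removed (adjusted p = 0.53 with an estimated correlation).

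Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split was 1 of 10 for genes changed (7760, highest other 0), genes higher (3711, highest other 0), genes lower (4049, highest other 0) and genes changed at least 2-fold (4601, highest other 0). Every other split mixes the groups, so a difference between the groups widens its spread. Counts of 0 there are therefore not a reference for libraries without a difference. For shifted lists, 9 of 10 splits gave at least the 14 of the real one, and the highest other gave 23. At the preset correlation the count of lists therefore does not set the real split apart. The other splits hold unequal numbers of the 2 groups, so part of a group difference can enter them. Their list counts are thus no reference for libraries without a difference either.

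Higher myelin and lipid synthesis genes stood beside lower repair, macrophage and proliferation genes. A larger share of Schwann cells in an unchanged state would raise both Schwann cell lists. The repair list had a median of -1.64 (95% bootstrap interval -4.47 to -1.01 over genes, not libraries). That argues against such a share as the whole cause. Lower repair genes were part of the pattern when this test was chosen, so it adds no independent support. It cannot decide on a larger share of Schwann cells with fewer repair transcripts each. The lineage genes Sox10 (1.26) and Erbb3 (0.49) rose, so a larger share as part of the cause stays open. A few abundant transcripts taking counts from the rest are also argued against: without the 10 most abundant genes, scaled by the remaining totals, the cholesterol list kept a median of 2.38 (1.91 to 2.74) and the proliferation list -3.58 (-4.05 to -2.92). Library or sequencing batch cannot be told apart from treatment: 0 of the 5 batch labels hold both groups, and although libraries of 1 group with different labels correlated at 0.970 or above over all genes, against at most 0.911 between groups, the 5 labels can be parted in only 10 ways. The conduit stays open as an untested biological explanation, as does time after injury, which the labels do not give.

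Of 16 skeletal muscle genes 12 were lower in conduit nerves, although the list did not pass (camera adjusted p = 0.409) and untreated replicate 3 held 20.04 CPM of muscle markers, below the 32.8 to 35.4 CPM of the conduit libraries. Muscle tissue in the untreated replicate 1 library was tested as the cause: its median muscle gene stood 190 times above the other untreated libraries, but without it 7 of 16 genes were lower, above the limit of 4 set beforehand, and 4 were higher. The list median went from -7.63 to -2.02. Untreated replicate 2 shares the batch number of untreated replicate 1, so muscle signal in it may not be independent of that library. The test therefore does not decide whether untreated replicate 1 is the whole cause of the lower genes. With conduit replicate 1, 2 or 3 left out only 1 gene passed as lower, but the list medians were -8.27, -7.80 and -8.28, so the calls ended while the fold did not shrink. Untreated replicate 2 still held 110 CPM of muscle markers, and what the remaining difference comes from was not tested.

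RT1-A3, an MHC class I gene, had 3307, 9 and 2833 counts in untreated replicates 1, 2 and 3 and 54, 5 and 7 in the conduit libraries. More antigen-presenting cells in the 2 high libraries are argued against, since RT1-A3 stood 376 times above untreated replicate 2 there, while the median of 17 other class I genes was 1.85 times and of the macrophage list 1.22 times. Different MHC haplotypes among the rats, read against 1 reference haplotype, may be a source. Beyond RT1-A3, 1 other class I gene, RT1-CE16, spread over 10-fold within a group (102 to 9932 counts in untreated and 41 to 4967 in conduit libraries), too few to decide. The call of RT1-A3 (-6.24 ± 1.80, adjusted p = 0.0230, and -8.08 without conduit replicate 1) was lost without conduit replicate 2 (0.0782) or 3 (0.0729).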
